A study of Rattus norvegicus with 39 samples.

How the data were processed

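Transcript abundance was measured with Affymetrix arrays in CA1 tissue of the hippocampus from 39 male Fischer 344 rats, 1 array per animal, aged 18 months at the end of the study per the labels. The 4 groups were Sham (10 arrays), LowCORT (10), IntermediateCORT (9) and LowCORT plus injections (10, called the injected group). Per the labels' protocols, total RNA was extracted from each block of CA1 tissue and turned into biotin-labelled cRNA. The deposited series table holds log2 expression values for 8799 probe sets on each array, ranging from 2.82 to 14.37. The base of the logarithm was read from the values, since a 16-bit scanner maximum has a natural logarithm of 11.09 and a log10 of 4.82, both below the highest value in the table. MAS5, RMA and R version 2.7.1 are named without a role per the submitters' processing notes, and which of them made these values is not given in the sources used here. The array medians lay between 7.27 and 7.33 and the upper quartiles between 8.52 and 8.67, so the arrays had been brought to nearly a common distribution. No further normalization was applied.

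Each array was assigned to its group from the labels. Subject numbers run from 1 to 39, group by group, and each belongs to a single animal, so no pairing or block entered the design, and the labels give no batch, scan date or day of death for an animal. The 59 control probe sets were left out of the tests. Of the other 8740 probe sets, 7006 carried 1 gene symbol in the platform table used here, 308 carried several and 1426 carried none, and the probe sets with 1 symbol stood for 4736 genes. Entrez identifiers of 6994 of the 7006 matched the gene table of the rat assembly GRCr8, which changed 0 symbols. No gene was named from a probe set with several symbols or none. Probe sets were tested when their mean over all arrays was at or above the 30th percentile, a log2 value of 6.28. This left 6118 probe sets, which covered 3620 genes with 1 symbol each.

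Differences between groups were tested with limma 3.58.1 in R 4.3.3, with 1 mean per group, all 39 arrays in the model, moderated variances and 35 residual degrees of freedom. The 6 comparisons between groups and a moderated F test over the 4 groups were each adjusted by the Benjamini-Hochberg method over the 6118 probe sets, and a probe set was called changed at an adjusted p under 0.05. All adjusted p-values of single genes are from limma, and all tests are two-sided. Errors of fold changes are standard errors (SE) from limma, and group values are means ± SD. These values compare animals, and the number of arrays limits their precision. The arrays hold no read depth.

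Gene lists were tested with camera at a preset correlation between genes of 0.01, using for each gene the probe set with the highest mean, and adjusted over the 186 pairs of 31 lists and 6 comparisons. The same test with the correlation estimated for each list, and the directional and mixed tests of fry, stand beside it. The 31 lists covered glucocorticoid-induced targets, corticosteroid receptors and their regulators, immediate early genes, circadian clock, cholesterol synthesis, oxidative phosphorylation, glycolysis and glucose use, cytosolic ribosomal proteins, heat shock and unfolded protein response, glutamate receptors and postsynaptic scaffold, presynaptic vesicle machinery, ion channels and calcium handling, GABA receptors, interferon response, MHC class I and II, extracellular matrix, cell cycle, and insulin and growth factor signalling. Cell type lists covered microglia and macrophages, astrocytes, oligodendrocytes and myelin, oligodendrocyte precursors, endothelial cells and pericytes, choroid plexus and ependyma, fibroblasts and meninges, blood cells, dentate gyrus granule neurons, CA3 and CA2 pyramidal neurons, CA1 pyramidal neurons, interneurons, and neighbouring forebrain regions. Counts of called members are given over all probe sets tested and adjusted over the list alone.

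The groups, comparisons, tests, lists, filter, most of the other settings and the rule for named genes were fixed before the data were examined. The rule named, for each comparison, up to 10 genes with the largest rise and up to 10 with the largest fall among called probe sets with 1 symbol, up to 4 members of each list with the smallest p, and the fixed genes Nr3c1, Nr3c2, Hsd11b1, Fkbp5, Sgk1, Tsc22d3, Per1, Klf9 and Pdk4. The 10 genes with the smallest p in the F test were added. From these, the text gives the genes that fit each paragraph. Fkbp5, Tsc22d3 and Per1 had 0 probe sets with that symbol alone in the table used here, and the probe set of Pdk4 fell below the filter.

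Comparisons that share the LowCORT arrays were set against data simulated with no effect, against the overlap of independent lists, and against 100 random divisions of the LowCORT arrays into groups of 5. The same simulations and divisions gave the sign and size of the opposing change over probe sets chosen on LowCORT against Sham. Signal quality was described by the difference between the 3' and 5' probe sets of the Gapdh and beta-actin controls, limma array weights and principal components of the residuals. Relations across arrays were tested with 100000 permutations. The results were also computed with quantile normalization, median centring, no filter, a filter at the 50th percentile, array weights, a trended robust prior, a model of the 2 groups alone, an unmoderated F test, averaged probe sets per gene, the other list tests and an unadjusted p of 0.01 for the overlap. Settings with the 3' to 5' differences as covariates, with a block by subject number and without 4 arrays of low weight were added after the data had been seen. The closing section gives the effect of each.

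The procedure was tested on simulated data of 6118 probe sets, with 200 of them changed. For LowCORT against Sham it recovered 70.1% of changes of 0.3 on the log2 scale, 94.0% of those of 0.6 and 100% of those of 1, and 7.85% of its calls were false. In the same order of sizes it recovered 68.7%, 95.5% and 98.5% for IntermediateCORT against Sham (4.89% false), 61.2%, 100% and 100% for IntermediateCORT against LowCORT (6.45%), 62.7%, 97.0% and 100% for injected against LowCORT (2.81%), 64.2%, 94.0% and 100% for injected against IntermediateCORT (4.97%), and 62.7%, 94.0% and 98.5% for injected against Sham (5.03%). A simulated shift of 0.2 in a single list was called in 3 of 3 comparisons, with 0 other pairs called. The simulated noise was independent between probe sets, without the correlation between genes on the real arrays. These rates therefore need not hold on the real arrays, where random assignments to the groups called a median of 11 list pairs. Figures were drawn with matplotlib 3.10.9 in Python 3.11.15.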

Results

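The 39 arrays measured transcripts in hippocampal CA1 of rats that differed in their exposure to corticosterone, the main glucocorticoid of the rat. Sham animals (n = 10) kept their adrenal glands and received an inert pellet. The other animals had their adrenal glands removed and received slow-release corticosterone for 3 months. LowCORT animals (n = 10) carried a 25 mg pellet and IntermediateCORT animals (n = 9) a 200 mg pellet. The injected group (n = 10) carried the 25 mg pellet and received 5 mg of corticosterone per day by injection on 4 days just before the end. Per the labels, animals with the low pellet went on drinking saline with sucrose, so the drinking fluid differed along with the dose. The study asked which hippocampal transcripts depend on glucocorticoids and how this relates to aging. All animals here were of 1 age, so aging itself was not compared.

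Arrays of a group correlated with each other at 0.944 to 0.996 across probe sets (median 0.983), and arrays of different groups at 0.944 to 0.997 (median 0.983), so arrays were no closer within groups than between them. No array was a copy of another. After group means were removed, a first component held 26.2% of the remaining variance. Its scores were related to the Gapdh difference between 3' and 5' probe sets, a sign of RNA or cDNA length, over the 39 arrays (Pearson's r = 0.764, Spearman's rho = 0.848). Both permutation p-values were 1e-05, the smallest the permutations can give, with adjusted values of 4.0e-05 and 2.67e-05 among 8 relations. Without the 2 arrays farthest from the median Gapdh difference r was 0.819, and within the groups it was 0.878 in Sham, 0.878 in LowCORT, 0.816 in IntermediateCORT and 0.771 in the injected group. The same component was related to the order of subject numbers within a group (r = 0.725, rho = 0.703, both permutation p = 1e-05, adjusted p = 4.0e-05 and 2.67e-05). That r was 0.689 without the 2 arrays at the ends of the order, and within the groups it was 0.821, 0.548, 0.789 and 0.768 in the same sequence. A second component held 21.1% of the remaining variance. It was related to the beta-actin difference (r = 0.632, rho = 0.637, permutation p = 5.2e-04 and 6.0e-05, adjusted p = 8.32e-04 and 9.6e-05), with r = 0.608 without the 2 farthest arrays and 0.653, 0.409, 0.694 and 0.686 within the groups. The second component showed no relation to the Gapdh difference (r = -0.231, rho = -0.081, permutation p = 0.29 and 0.652). It was also related to subject order (r = 0.474, rho = 0.658, permutation p = 0.00251 and 1e-05, adjusted p = 0.00335 and 2.67e-05), with r = 0.469 without the 2 ends and 0.310, 0.863, 0.872 and 0.367 within the groups. The beta-actin difference itself went with subject order (r = 0.682, rho = 0.674, both permutation p = 2.0e-05, adjusted p = 5.33e-05 and 4.0e-05), with r = 0.655 without the 2 ends and 0.697, 0.642, 0.783 and 0.714 within the groups. The mean Gapdh difference was 0.70 ± 0.22 in Sham (SD, n = 10), 0.81 ± 0.24 in LowCORT, 0.63 ± 0.21 in IntermediateCORT (n = 9) and 1.03 ± 0.60 in the injected group. No group pair passed for it or for the beta-actin difference by permutation tests, with a lowest adjusted p of 0.393 among 12 tests. This does not show that the groups were equal. The injected group exceeded IntermediateCORT by 0.40 in the Gapdh difference (unadjusted permutation p = 0.0642).

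**Figure D1:**
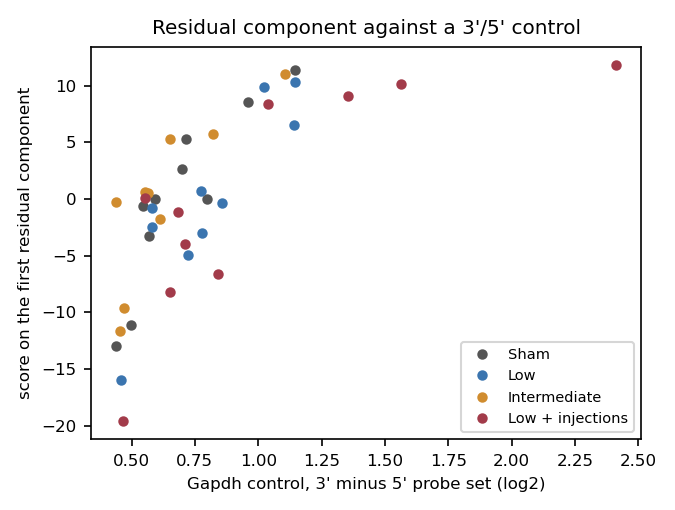
Score of each of the 39 arrays on the first component of the residuals (vertical axis, no unit) against the log2 difference between the 3' and 5' Gapdh control probe sets (horizontal axis), coloured by group. Scores and Gapdh differences went together over all arrays with r = 0.764, and arrays of all 4 groups lie along the relation.

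Among the 4 groups, 139 of 6118 probe sets changed by limma's moderated F test, and 719 had an unadjusted p under 0.05. The 10 genes with the smallest p were Car4, a membrane-bound carbonic anhydrase, Sult1a1, a sulfotransferase of phenols and steroids, Hk2, a hexokinase, Sgk1, the serum- and glucocorticoid-regulated kinase, Slfn5, Serpinh1, Tnfrsf11b, Ifitm3, Csrp2 and S100a4. Their adjusted p ranged from 1.3e-07 for Car4 to 1.03e-04 for S100a4. The differences between LowCORT and the groups with more corticosterone held the most calls, as the plot of changed probe sets per comparison shows.

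**Figure D2:**
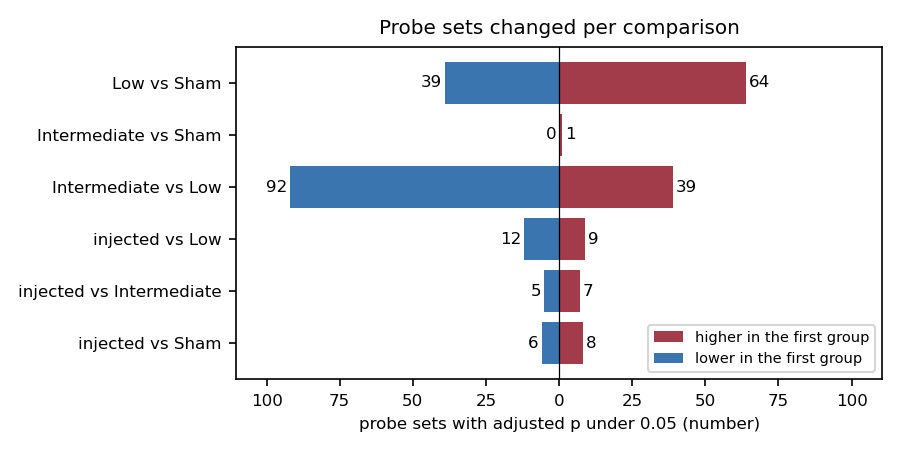
Number of probe sets with a limma adjusted p under 0.05 in each of the 6 comparisons (horizontal axis), with bars to the right for probe sets higher and to the left for those lower in the group named first. LowCORT differed from Sham in 64 and 39 probe sets and IntermediateCORT from LowCORT in 39 and 92, while IntermediateCORT differed from Sham in 1 and 0.

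In CA1 of rats without adrenal glands on the low pellet, genes that glucocorticoids induce were lower than in intact rats, and genes of the interferon response were higher. Sgk1 fell the most, from 9.43 ± 0.59 in Sham (SD, n = 10) to 7.93 ± 0.17 in LowCORT (n = 10), a log2 fold change of -1.50 (SE 0.17, adjusted p = 2.9e-07) or 2.83-fold. Within Sham, Sgk1 differed along the order of subject numbers, at 9.53 to 10.25 in animals 1 to 5 and 8.45 to 9.41 in animals 6 to 10. The highest LowCORT value was 8.27, so the direction holds for both sets, while the size depends on them. Sult1a1 fell 1.97-fold (log2 -0.98, SE 0.12, adjusted p = 3.33e-07) and Calb1, the calcium-buffering protein calbindin, fell 1.53-fold (-0.61, SE 0.11, adjusted p = 4.57e-04). Each of the 10 LowCORT animals lay below the Sham mean for these 3 genes. Ifitm3, an interferon-induced membrane protein that restricts virus entry, rose 1.57-fold (0.65, SE 0.09, adjusted p = 2.64e-06), above the Sham mean in 10 of 10 animals. In all, 64 probe sets rose and 39 fell, with 88 of the 103 carrying 1 symbol and standing for 82 genes.

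Of 15 tested glucocorticoid-induced targets, 0 rose, 5 fell and 10 did not pass, and 8 fell when adjusted over the list alone. All 15 had negative values, and the list fell as a whole (camera adjusted p = 5.71e-11, and 4.96e-04 with an estimated correlation). Beside Sgk1 and Sult1a1, the members with the smallest p among those that fell were the interleukin-6 receptor Il6r (-0.47, adjusted p = 3.25e-04) and Nfkbia, the inhibitor of NF-kB (-0.30, adjusted p = 0.0117). Errfi1, a brake on the epidermal growth factor receptor, fell by 0.46 in 1 probe set (adjusted p = 4.62e-04), while the probe set that stands for it on the list had -0.23 and did not pass. Klf9, another classical target, had -0.31 but did not pass (adjusted p = 0.0614). Of the receptors, the mineralocorticoid receptor Nr3c2 rose by 0.44 (SE 0.11, adjusted p = 0.0218), while the glucocorticoid receptor Nr3c1 had a log2 fold change that rounds to 0.00 (adjusted p = 0.99) and the steroid-activating enzyme Hsd11b1 had -0.09 (adjusted p = 0.676). The call of Nr3c2 did not hold with array weights (0.36, adjusted p = 0.0748).

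All 10 tested interferon response genes had positive values and the list rose (adjusted p = 1.56e-05, and 4.96e-04 with an estimated correlation). Ifitm3 and Irf7, a transcription factor that drives interferon production (0.32, adjusted p = 0.0191), rose, and 4 members rose when adjusted over the list alone. The immunoproteasome subunit Psmb8 had 0.19 (adjusted p = 0.0647). Slfn5, of the interferon-inducible schlafen family and not on the list, rose by 0.60 (SE 0.08, adjusted p = 3.08e-06). Among 16 markers of microglia and macrophages, 1 rose and 15 did not pass, and 4 rose when adjusted over the list alone. The member that rose was Fcgr2b, an inhibitory receptor for immunoglobulin G (0.54, adjusted p = 9.51e-04), while Cd53 had 0.21 (adjusted p = 0.0626) and complement C3 had 0.36 (adjusted p = 0.0975). The microglial list rose with the preset correlation (adjusted p = 0.00965) and not with an estimated one (adjusted p = 0.145 with an estimated correlation). Probe sets of Aif1, a microglial calcium-binding protein, differed. The most significant had 0.53 (adjusted p = 0.0396) and the lowest of 3 had -0.05. MHC class I and II genes, of which 0 of 11 passed, rose as a list (adjusted p = 0.045, and adjusted p = 0.199 with an estimated correlation), with B2m at 0.24 (adjusted p = 0.124). They numbered 3 risen when adjusted over the list alone.

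Markers of inhibitory interneurons fell in LowCORT. Of 15 members, 2 fell and 13 did not pass, 6 fell when adjusted over the list alone, and 13 had negative values (adjusted p = 6.2e-05, and 0.0385 with an estimated correlation). The members that fell were Gad1, the enzyme that makes GABA (-0.31, SE 0.07, adjusted p = 0.00758), and the calcium-binding protein Calb2 (-0.23, SE 0.05, adjusted p = 0.0135). Cholesterol synthesis genes fell with 2 of 13 members called and 5 when adjusted over the list alone (adjusted p = 0.00219, but adjusted p = 0.1 with an estimated correlation). These were Sqle, squalene epoxidase (-0.26, adjusted p = 0.033), and Insig1, which holds back sterol synthesis and whose transcript follows the pathway (-0.28, adjusted p = 0.043). Presynaptic vesicle genes fell with 0 of 20 members called and 1 when adjusted over the list alone (adjusted p = 0.0338, but adjusted p = 0.41 with an estimated correlation). Cplx1 had -0.45 (adjusted p = 0.0771) and Rab3a -0.37 (adjusted p = 0.143). The mean Gapdh difference between 3' and 5' was 0.81 in LowCORT and 0.70 in Sham, and with the 3' to 5' covariates the list mean went from -0.16 (SE 0.08) to -0.10 (SE 0.05), with an adjusted p of 0.0341 by the preset test. Glycolysis and glucose use fell with 0 of 26 members called and 0 when adjusted over the list alone (adjusted p = 0.049, and adjusted p = 0.0934 with an estimated correlation), as did oxidative phosphorylation with 0 of 32 and 0 (adjusted p = 0.04998, and adjusted p = 0.552 with an estimated correlation). Hk2 rose by 0.63 (SE 0.07, adjusted p = 3.74e-08) in 1 probe set and had -0.14 in the other, which stands for it on the glycolysis list.

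Slco1a4, a transporter of the blood-brain barrier, rose by 0.56 (SE 0.10, adjusted p = 4.21e-04), Car4 by 0.53 (SE 0.05, adjusted p = 2.81e-08) and Vim, an intermediate filament of astrocytes and vessel cells, by 0.60 (SE 0.13, adjusted p = 0.0049). The calcium-binding S100a4 rose by 0.65 (adjusted p = 3.08e-05) and the LIM protein Csrp2 by 0.57 (adjusted p = 6.44e-06). Dcn, the matrix proteoglycan decorin, was higher in all 3 of its probe sets, from 0.27 to 0.48, and 2 of them passed. Mgp (0.24, adjusted p = 0.00821) and Enpp2, the enzyme autotaxin (0.40, adjusted p = 0.0409), also rose. The lists of endothelial cells and pericytes (adjusted p = 0.131), extracellular matrix (adjusted p = 0.824), astrocytes (adjusted p = 0.763) and fibroblasts and meninges (adjusted p = 0.4934) did not pass in this comparison. The 6 tested CA1 pyramidal markers rose with 2 members called and 2 when adjusted over the list alone (adjusted p = 0.0395, but adjusted p = 0.361 with an estimated correlation), and these members were Dcn and Nr3c2. Further falls included Itih3, a carrier of hyaluronan (-0.64, adjusted p = 0.00812), angiotensinogen Agt (-0.41, adjusted p = 0.00773), the retinoic acid-binding Crabp1 (-0.41), the potassium channel Kcnk1 (-0.40) and the melanin-concentrating hormone receptor Mchr1 (-0.39). The clock-controlled transcription factor Dbp rose by 0.39 (adjusted p = 0.00782). Counts moved most with the 3' to 5' differences as covariates, to 175, of which 100 were among the 103.

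**Figure D3:**
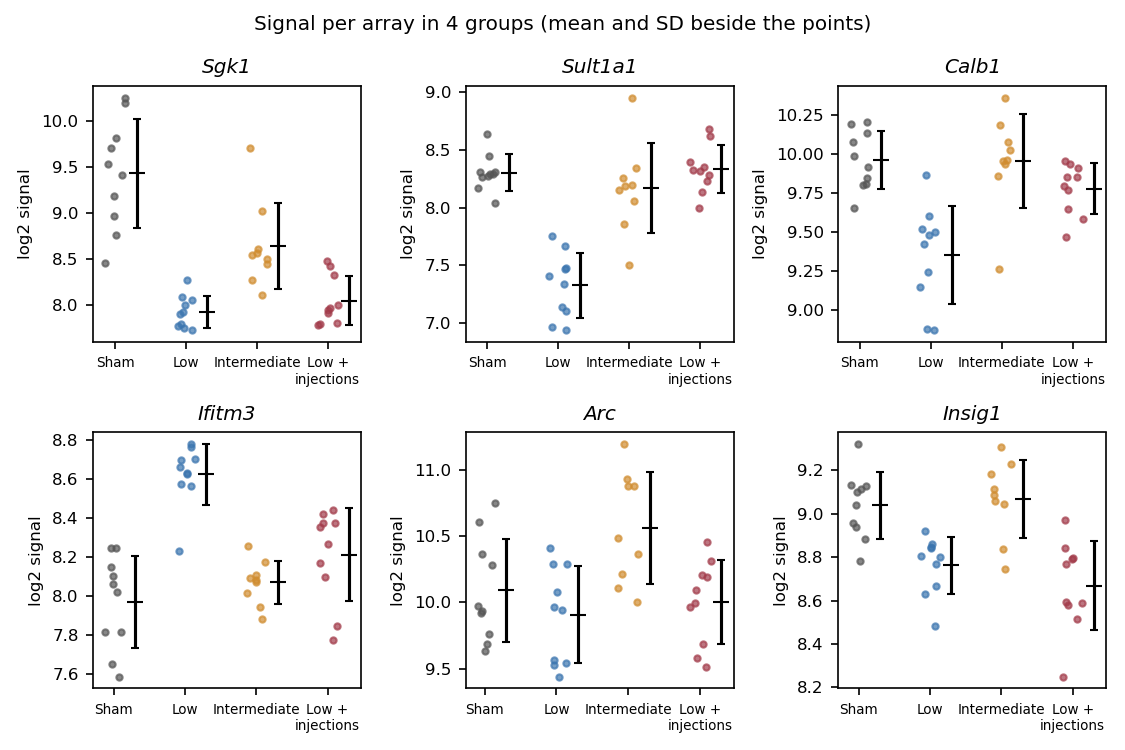
Log2 signal (vertical axis) of Sgk1, Sult1a1, Calb1, Ifitm3, Arc and Insig1 on each array of the 4 groups, with the mean and SD beside the points. Sgk1 averaged 9.43 in Sham, 7.93 in LowCORT, 8.64 in IntermediateCORT and 8.05 in the injected group.

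With the larger pellet in place of the low pellet, 39 probe sets rose and 92 fell in CA1, and 117 of the 131 carried 1 symbol, for 105 genes. Sult1a1 rose 1.79-fold (log2 0.84, SE 0.12, adjusted p = 3.06e-05), Sgk1 1.64-fold (0.71, SE 0.18, adjusted p = 0.0213) and Calb1 1.52-fold (0.60, SE 0.11, adjusted p = 9.04e-04). Slfn5 fell 1.59-fold (-0.67, SE 0.08, adjusted p = 2.67e-06) and Ifitm3 1.47-fold (-0.55, SE 0.09, adjusted p = 1.14e-04). All 9 IntermediateCORT animals lay on the same side of the LowCORT mean for Sult1a1, Sgk1, Slfn5 and Ifitm3, and 8 of 9 did for Calb1. This comparison addressed the dose held for 3 months, together with the drinking fluid, which differed along with the dose.

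Glucocorticoid-induced targets rose as a list, with 3 of 15 members up, 0 down and 12 not passing, 6 up when adjusted over the list alone, and 11 positive values (adjusted p = 3.32e-06, and 0.0134 with an estimated correlation). The third member was Il6r (0.46, adjusted p = 8.14e-04). Interferon response genes fell, with 1 of 10 called, 7 when adjusted over the list alone and 9 negative values (adjusted p = 1.72e-06, and 2.76e-04 with an estimated correlation). Irf7 had -0.28 (adjusted p = 0.0583). Microglial markers fell with 2 of 16 called and 8 when adjusted over the list alone (adjusted p = 2.11e-04, and 0.0296 with an estimated correlation). These were Fcgr2b (-0.60, SE 0.10, adjusted p = 4.12e-04) and Cd53, a leukocyte surface protein (-0.25, SE 0.06, adjusted p = 0.0229). Aif1 again had 1 probe set of 3 that passed, at -0.54 (adjusted p = 0.0335), with the highest of the 3 at a value that rounds to 0.00.

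Among the largest rises with the larger pellet, Arc, which moves glutamate receptors at synapses, rose by 0.66 (SE 0.16, adjusted p = 0.0207) and the activity-induced transcription factor Nr4a1 by 0.60 (SE 0.14, adjusted p = 0.0116). Immediate early genes rose with 2 of 18 members called, and 5 up and 1 down when adjusted over the list alone (adjusted p = 0.0166, but adjusted p = 0.422 with an estimated correlation), while Jun had -0.35 in the probe set used for the list (adjusted p = 0.0715) and 2 of its 4 probe sets fell. Wipf3, a regulator of actin assembly, rose by 0.83 (SE 0.15, adjusted p = 8.21e-04), the dendritic spine kinase Itpka by 0.58 (adjusted p = 0.00982), the calcium sensor Hpca by 0.53 (adjusted p = 0.00632) and S100a10 by 0.61 (adjusted p = 0.00784). Itih3 rose by 0.71 (adjusted p = 0.00315). Ion channel and calcium handling genes rose with 1 of 31 called, Calb1, and 4 when adjusted over the list alone (adjusted p = 0.0062, but adjusted p = 0.109 with an estimated correlation). Cholesterol synthesis rose with 2 of 13 called and 4 when adjusted over the list alone (adjusted p = 0.00161, but adjusted p = 0.0934 with an estimated correlation). Its called members were Insig1 (0.30, adjusted p = 0.0229) and Fdft1, squalene synthase (0.38, adjusted p = 0.0477). Interneuron markers rose with 0 of 15 called and 0 when adjusted over the list alone (adjusted p = 0.049, but adjusted p = 0.307 with an estimated correlation).

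Vessel and myelin lists and some matrix genes were lower with the larger pellet, while the extracellular matrix list did not pass (adjusted p = 0.238). Endothelial and pericyte markers fell with 2 of 16 called and 2 when adjusted over the list alone (adjusted p = 0.0376, but adjusted p = 0.282 with an estimated correlation), namely Slco1a4 (-0.59, adjusted p = 3.52e-04) and the pericyte potassium channel Kcnj8 (-0.63, adjusted p = 0.0452). Oligodendrocyte and myelin genes fell with 1 of 11 called and 2 when adjusted over the list alone (adjusted p = 0.049, but adjusted p = 0.492 with an estimated correlation), the called member being the myelin enzyme Cnp (-0.28, adjusted p = 0.0137). Oligodendrocyte precursor markers fell with 0 of 4 called and 1 when adjusted over the list alone (adjusted p = 0.049, but adjusted p = 0.231 with an estimated correlation). Dcn fell in all 3 probe sets, from -0.54 to -0.37. Vim fell by 0.48 (adjusted p = 0.036), Enpp2 by 0.44 (adjusted p = 0.0207), Mgp by 0.23 (adjusted p = 0.0133) and S100a4 by 0.54 (adjusted p = 9.91e-04). Heme oxygenase Hmox1 fell by 0.57 (adjusted p = 0.0335) and Map3k1, a kinase of stress signalling, by 0.57 (adjusted p = 0.0095), each in 1 of its probe sets. Nr3c2 had -0.36 (adjusted p = 0.096). With array weights the count of changed probe sets was 338. Kcnj8 did not pass under 5 alternatives, among them median centring (-0.63, adjusted p = 0.0519).

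Set against intact rats, rats on the larger pellet differed in 1 probe set. It carries no symbol in the table used here (AF030088UTR#1_at) and rose by 1.10 on the log2 scale (SE 0.17, adjusted p = 4.32e-04). Limma called 0 probe sets as fallen, 258 had an unadjusted p under 0.05 in either direction, the model of the 2 groups alone called 4 in all, and the model with the 3' to 5' covariates called 12. Sgk1 stood at 8.64 ± 0.47 (SD, n = 9) against 9.43 ± 0.59 in Sham (n = 10), a log2 difference of -0.79 (SE 0.18) that did not pass (adjusted p = 0.165). With the 3' to 5' covariates it was -0.78 and passed (adjusted p = 0.0461).

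A set of 4 lists passed in IntermediateCORT against Sham with the preset correlation, and 0 of them with an estimated one. Immediate early genes rose (adjusted p = 1.3e-04, but adjusted p = 0.244 with an estimated correlation), with 0 of 18 members called and 3 when adjusted over the list alone. Arc had 0.47 (adjusted p = 0.824), Nr4a1 0.39 (adjusted p = 0.824) and the phosphatase Dusp6 0.36 (adjusted p = 0.67). Glucocorticoid-induced targets fell (adjusted p = 0.0116, but adjusted p = 0.199 with an estimated correlation), with 0 of 15 called, 1 when adjusted over the list alone and 12 negative values. Nfkbia had -0.20 (adjusted p = 0.824). Interneuron markers fell (adjusted p = 0.0174, but adjusted p = 0.231 with an estimated correlation), with 0 of 15 called and 2 when adjusted over the list alone, Calb2 at -0.21 (adjusted p = 0.313) and Gad1 at -0.20 (adjusted p = 0.824). Extracellular matrix genes fell (adjusted p = 0.049, but adjusted p = 0.324 with an estimated correlation), with 0 of 23 called and 0 when adjusted over the list alone. Camk2a, a kinase of synaptic plasticity, had 0.50 (adjusted p = 0.184) and passed under 4 alternatives, among them the 2 groups alone (adjusted p = 0.0468). Interferon response genes had a mean log2 fold change of -0.0038 and did not pass (adjusted p = 0.795).

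With injections of corticosterone on 4 days over the low pellet, 9 probe sets were higher and 12 lower than in LowCORT. No group is labelled as injected with vehicle, so injection and handling cannot be told apart from the corticosterone itself. Sult1a1 rose 2.01-fold (log2 1.01, SE 0.12, adjusted p = 3.18e-07), from 7.33 ± 0.28 in LowCORT (SD, n = 10) to 8.33 ± 0.20 in the injected group (n = 10). Sgk1 had 0.12 (SE 0.17, adjusted p = 0.883), with 6 of 10 injected animals above the LowCORT mean. Ifitm3 fell by 0.41 (SE 0.09, adjusted p = 0.015) and Slfn5 by 0.35 (SE 0.08, adjusted p = 0.0293). Car4 fell by 0.34 (SE 0.05, adjusted p = 4.46e-04) in both of its probe sets. The total of 21 was 50 with array weights and 33 with the subject block, and a random split of the same arrays called up to 107.

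Interferon response genes fell (adjusted p = 4.64e-04, and 0.00304 with an estimated correlation), with 1 of 10 members called, 1 when adjusted over the list alone and 9 negative values. MHC genes fell with 0 of 11 called and 0 when adjusted over the list alone (adjusted p = 0.0237, but adjusted p = 0.174 with an estimated correlation). Glucocorticoid-induced targets rose with 1 of 15 called, Sult1a1, and 1 when adjusted over the list alone (adjusted p = 0.0192, but adjusted p = 0.236 with an estimated correlation). Among single genes, complement C3 fell by 0.52 (adjusted p = 0.0237), Fcgr2b by 0.43 (adjusted p = 0.037), the kallikrein protease Klk6 by 0.45 (adjusted p = 0.0249), the adenylate kinase Ak4 by 0.36 (adjusted p = 0.0237) and the collagen chaperone Serpinh1 by 0.27 (adjusted p = 5.51e-04). Dcn fell by 0.46 in 1 probe set (adjusted p = 0.0385), and the lowest and highest of its 3 probe sets were -0.46 and -0.25. The carboxypeptidase inhibitor Lxn fell by 0.42 (adjusted p = 0.00148), to a level below that of the other 3 groups.

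Genes that rose with the injections included Agt (0.38, adjusted p = 0.037), the taurine-synthesis enzyme Csad (0.37, adjusted p = 0.0249), the galectin-related Grifin (0.34, adjusted p = 5.51e-04), Ncdn (0.28, adjusted p = 0.037) and the neuropeptide galanin, Gal (0.23, adjusted p = 0.0237). Ncdn did not pass under 5 alternatives, among them array weights (0.19, adjusted p = 0.106). Blood cell genes rose (adjusted p = 0.00246, but adjusted p = 0.0871 with an estimated correlation), with 1 of 6 called and 3 when adjusted over the list alone. The called member was Alas2, the heme synthesis enzyme of red cells (0.31, adjusted p = 0.037), while the hemoglobin genes Hbb and Hbb-b1 had 0.66 (adjusted p = 0.488) and 0.58 (adjusted p = 0.3). Interneuron markers rose with 0 of 15 called and 3 when adjusted over the list alone (adjusted p = 0.045, but adjusted p = 0.293 with an estimated correlation). Cholesterol synthesis fell with 0 of 13 called and 1 when adjusted over the list alone (adjusted p = 0.04998, but adjusted p = 0.282 with an estimated correlation), with Cyp51 at -0.30 (adjusted p = 0.052) and 1 of its 5 probe sets above 0. Calb1 had 0.42 (adjusted p = 0.0663), the clock repressor Nr1d1 0.41 (adjusted p = 0.0524) and Nr3c2 -0.28 (adjusted p = 0.526).

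The responses to the larger pellet and to the injections, each measured over the same LowCORT arrays, shared 14 probe sets called in the same direction, 4 up and 10 down, and 0 in opposite directions. Independent lists of these sizes would share 0.238, and data simulated without effects shared a mean of 0. Data without effects hold few called probe sets, so that 0 is no reference for shared calls. Dividing the LowCORT arrays between the comparisons left a median of 5 (2 to 9 over 100 draws), and the lists themselves shrank to medians of 48.5 and 8 calls. Across probe sets the fold changes had a covariance of 0.0046 against 0.00475 simulated with shared controls alone, a difference of -1.44e-04, and a correlation of 0.345 against 0.496. The simulation with shared controls thus gave as much covariance over all probe sets as was seen. With the LowCORT arrays divided, so that no array was shared, the covariance had a median of 0.00168. The correlation then had a median of 0.103, with a range of -0.317 to 0.391 over 100 draws. Since that range holds both signs, these values do not decide whether shared LowCORT arrays gave all of the covariance.

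LowCORT against Sham and IntermediateCORT against LowCORT shared 62 probe sets called in opposite directions (45 up and 17 down in LowCORT). Both comparisons use the LowCORT arrays. Independent lists would share 1.21, simulated data without effects 0, and divided LowCORT arrays a median of 20 (15 to 25), from lists with medians of 44 and 50 calls. As above, the simulated 0 is no reference for shared calls. With the sign of the latter comparison turned, the covariance was 0.0116 against 0.0047 simulated, a difference of 0.00693, and the correlation was 0.722 against 0.479. For the injected group, 15 were called in both in opposite directions (0.183 for independent lists, 0 simulated, a median of 6 and a range of 3 to 10 with divided arrays). The lists with divided arrays had medians of 44 and 8 calls. Its covariance was 0.00782 against 0.00491 simulated, a difference of 0.00291, with correlations of 0.593 and 0.508. With shared arrays the median ratio of the opposing change to the change from Sham was -0.873 for the larger pellet and -0.466 for the injections. Data simulated without effects gave -0.485 (-0.903 to -0.0736) and -0.505 (-0.913 to 0.00872). That simulation chose its probe sets from noise alone, so its range is no measure of what shared arrays add to called probe sets. With the LowCORT arrays divided, so that 5 chose the probe sets and the other 5 gave the opposing change, the ratio was -0.757 (-0.922 to -0.441 over 100 draws) and -0.409 (-0.603 to -0.127). Both ranges were negative with no array shared, which argues against shared arrays as the whole source of the opposing change. A total of 13 probe sets were called in all 3 comparisons. They stood for Klk6, Sult1a1, Serpinh1, Ak4, Slfn5, Dcn, Car4, Ifitm3 and Fcgr2b, and 3 of them had no single symbol.

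The injected group and the larger pellet differed in 12 probe sets, with 7 higher and 5 lower after injections. Fabp7, the brain fatty acid-binding protein of radial glia and astrocytes, was 1.77-fold higher (log2 0.83, SE 0.16, adjusted p = 0.0117), at 8.86 ± 0.42 (SD, n = 10) against 8.04 ± 0.30 (n = 9). The alarmin Il33 was higher by 0.62 (SE 0.11, adjusted p = 0.00492) and Rsad2, an antiviral interferon-induced enzyme, by 0.51 (SE 0.12, adjusted p = 0.037). Camk2a fell by 0.57 (SE 0.12, adjusted p = 0.0251) in 1 probe set and had -0.10 in the other. Insig1 fell by 0.40 (SE 0.08, adjusted p = 0.0117). All 10 injected animals lay on the same side of the IntermediateCORT mean for these 5 genes.

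Cholesterol synthesis was lower after injections than with the larger pellet. All 13 members had negative values, 1 was called and 6 fell when adjusted over the list alone (adjusted p = 2.39e-08, and 0.00171 with an estimated correlation), with Fdft1 at -0.44 (adjusted p = 0.0752). Blood cell genes were higher, with 6 of 6 values positive, 0 called and 3 when adjusted over the list alone (adjusted p = 5.15e-04, and 0.0385 with an estimated correlation). Hbb had 0.86 (adjusted p = 0.146), Hbb-b1 0.74 (adjusted p = 0.101) and Alas2 0.30 (adjusted p = 0.0752). Immediate early genes were lower with 0 of 18 called and 7 when adjusted over the list alone (adjusted p = 1.74e-04, but adjusted p = 0.245 with an estimated correlation). Arc had -0.56 (adjusted p = 0.146), Nr4a1 -0.52 (adjusted p = 0.111) and Egr2 -0.51 (adjusted p = 0.146). Presynaptic vesicle genes were lower with 0 of 20 called and 0 when adjusted over the list alone (adjusted p = 0.00664, but adjusted p = 0.307 with an estimated correlation), Snap25 having -0.24 (adjusted p = 0.495). The mean Gapdh difference between 3' and 5' was 1.03 in the injected group and 0.63 in IntermediateCORT, and with these covariates the presynaptic list had an adjusted p of 0.835 and the blood cell list an adjusted p of 2.46e-04.

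Glucocorticoid-induced targets were lower after injections than with the larger pellet, with 0 of 15 called and 5 when adjusted over the list alone (adjusted p = 0.0237, but adjusted p = 0.244 with an estimated correlation), and Sgk1 had -0.59 (adjusted p = 0.157). Ion channel genes were lower with 0 of 31 called and 0 when adjusted over the list alone (adjusted p = 0.0311, but adjusted p = 0.199 with an estimated correlation). Microglial markers were higher with 0 of 16 called and 1 when adjusted over the list alone (adjusted p = 0.0192, but adjusted p = 0.178 with an estimated correlation), with C1qb at 0.34 (adjusted p = 0.0612). Endothelial and pericyte markers were higher with 0 of 16 called and 1 when adjusted over the list alone (adjusted p = 0.0347, but adjusted p = 0.274 with an estimated correlation). Among further called genes, the membrane-bound metalloproteinase Mmp14 rose by 0.33 (adjusted p = 0.0368), the decoy receptor Tnfrsf11b by 0.30 (adjusted p = 0.0188) and Grifin by 0.27 (adjusted p = 0.0349). Cysteine dioxygenase Cdo1 fell by 0.47 (adjusted p = 0.0368) and the ERK phosphatase Dusp5 by 0.28 (adjusted p = 0.0419). With the 2 groups alone in the model limma called 0 of these, and with array weights it called 105.

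Against intact rats, the injected group had 8 probe sets higher and 6 lower. Sgk1 fell 2.61-fold (log2 -1.38, SE 0.17, adjusted p = 6.78e-06), to 8.05 ± 0.27 (SD, n = 10) from 9.43 ± 0.59 (n = 10), while Sult1a1 averaged 8.33 in the injected group and 8.30 in Sham. Errfi1 fell by 0.44 (SE 0.08, adjusted p = 0.00458) in 1 of its 2 probe sets, Nfkbia by 0.32 (SE 0.07, adjusted p = 0.0246) and Gpd1, glycerol phosphate dehydrogenase, by 0.20 (SE 0.05, adjusted p = 0.0467). Dbp rose by 0.48 (SE 0.09, adjusted p = 0.00458) in both of its probe sets. For each of these genes 10 of 10 injected animals lay on that side of the Sham mean.

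Cholesterol synthesis fell (adjusted p = 2.0e-11, and 2.76e-04 with an estimated correlation), with 2 of 13 called, 5 when adjusted over the list alone and 11 negative values. The called members were Insig1 (-0.37, adjusted p = 0.0119) and Sqle (-0.29, adjusted p = 0.0467), and Acat2 had -0.28 (adjusted p = 0.0889) and Msmo1 -0.26 (adjusted p = 0.0913). Glucocorticoid-induced targets fell (adjusted p = 2.39e-08, and 0.00274 with an estimated correlation), with Sgk1, Nfkbia and Gpd1 called of 15 members, 5 when adjusted over the list alone, and Il6r had -0.33 (adjusted p = 0.0771). Interneuron markers fell with 0 of 15 called and 0 when adjusted over the list alone (adjusted p = 0.0062, but adjusted p = 0.178 with an estimated correlation). Blood cell genes rose with 0 of 6 called and 3 when adjusted over the list alone (adjusted p = 0.00403, but adjusted p = 0.0934 with an estimated correlation), with Hbb at 0.72 (adjusted p = 0.398) and Alas2 at 0.25 (adjusted p = 0.201). Presynaptic vesicle genes fell with 0 of 20 called and 0 when adjusted over the list alone (adjusted p = 1.15e-04, but adjusted p = 0.178 with an estimated correlation). Snap25 had -0.32 (adjusted p = 0.705) and Cplx1 -0.31 (adjusted p = 0.746). With the 3' to 5' covariates that list had an adjusted p of 0.0755.

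Among further genes that rose against Sham, Fabp7 had 0.68 (adjusted p = 0.0436), Il33 0.51 (adjusted p = 0.0119), Rsad2 0.50 (adjusted p = 0.0416), Tnfrsf11b 0.31 (adjusted p = 0.00754) and Grifin 0.27 (adjusted p = 0.0156). Hk2 rose by 0.36 (adjusted p = 0.00458) in 1 probe set and had -0.10 in the other. With the 2 groups alone in the model 1 probe set was called, and Fabp7 did not pass (adjusted p = 0.131). Random splits of these arrays gave at least 14 calls in 5 of 100 draws, the real split included.

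**Figure D4:**
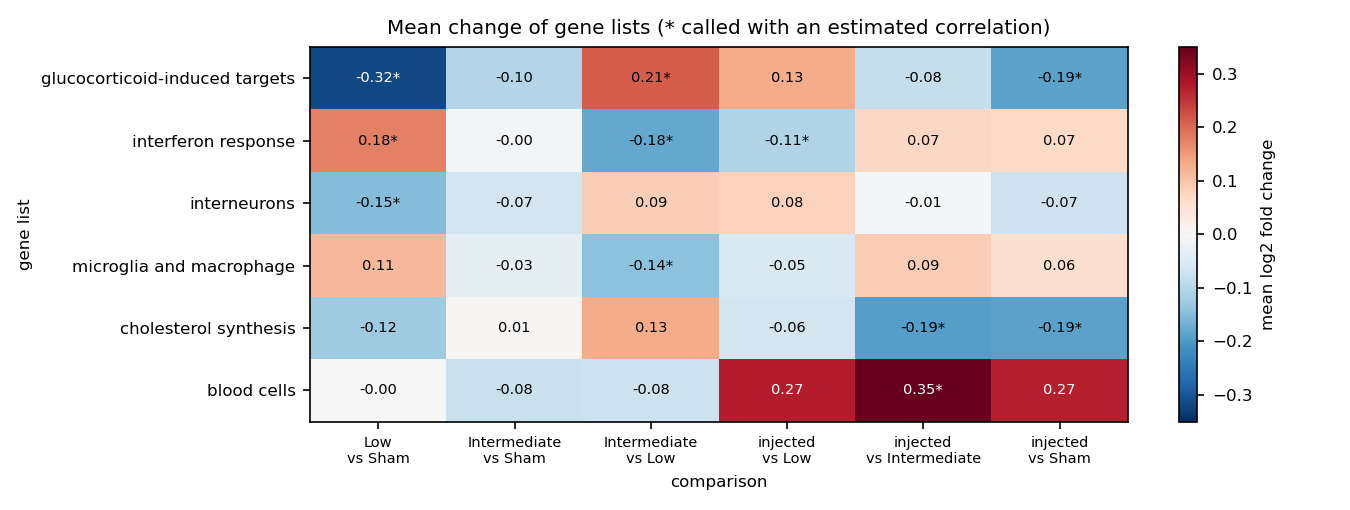
Mean log2 fold change of the 6 gene lists that passed with an estimated correlation in any comparison (rows) in the 6 comparisons (columns), with an asterisk where the list passed with the estimate. Glucocorticoid-induced targets ran from -0.32 in LowCORT against Sham to 0.21 in IntermediateCORT against LowCORT, and the interferon response from 0.18 to -0.18 in the same comparisons.

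Over the 186 pairs of list and comparison, 43 passed with the preset correlation and 11 with an estimated one, while fry called 28 in a direction and 3 in its mixed test. With the arrays assigned to the 4 groups at random, the preset test called a median of 11 pairs and the test with an estimated correlation a median of 0. Median, mean and test had the same sign in all 43 pairs and differed in sign in 31 of the other 143. A total of 14 lists passed in 0 of the 6 comparisons. Their lowest adjusted p was 0.0714 for CA3 and CA2 pyramidal neurons (IntermediateCORT against LowCORT), 0.084 for cell cycle, 0.129 for neighbouring forebrain regions and 0.191 for glutamate receptors and postsynaptic scaffold (all IntermediateCORT against Sham). It was 0.118 for astrocytes, 0.12 for circadian clock, 0.129 for fibroblasts and meninges and 0.304 for GABA receptors (all injected against Sham). It was 0.129 for dentate gyrus granule neurons, 0.154 for cytosolic ribosomal proteins, 0.293 for insulin and growth factor signalling and 0.457 for heat shock and unfolded protein response (all injected against LowCORT). It was 0.155 for choroid plexus and ependyma (injected against IntermediateCORT) and 0.482 for corticosteroid receptors and their regulators (LowCORT against Sham).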

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

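The tests of arrays of low weight, of the 3' to 5' signal and of the subject block were chosen after the results were seen, and so were the bounds for the splits. Among 340 groups of values, 85 measures in each of the 4 groups, 26 held an animal whose log2 value stood far from the others of its group, and chance alone gives about 1 in 20 such groups. The animals came from 14 arrays, and Sham animal 6 had the most, with 6. That animal had the lowest Itih3 (8.83, next 9.57), Aif1 (6.66, next 7.33), C3 (7.12, next 7.49) and Acat2 (8.66, next 8.97) in Sham and the highest Agt (10.57, next 10.21) and C1qb (10.19, next 9.85). LowCORT animal 20 had the lowest Agt (9.22) and Ifitm3 (8.23) of its group and the highest value of a Dcn probe set (9.86). LowCORT animal 22 had the lowest hemoglobin values, Hbb at 9.60 and Hbb-b1 at 9.32, and LowCORT animal 21 had the lowest Irf7 at 7.295. Other Sham animals stood apart for Crabp1 (animal 9, lowest at 6.45), Vim (animal 1, lowest at 6.91), Lxn (animal 1, lowest at 8.81) and Gal (animal 5, highest at 8.01). In IntermediateCORT, animal 11 was lowest for Calb1 (9.26) and Wipf3 (10.21) and animal 14 was highest for Crabp1 (7.26). In the injected group, animal 30 was highest for Kcnk1 (8.41), animal 34 for Itpka (11.63) and Grifin (7.73), animal 38 for Kcnj8 (7.63) and Map3k1 (8.40) and animal 35 for Jun (9.92). Injected animal 39 had the lowest mean of the interferon response list (7.52, next 7.60).

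A technical source of the 103 probe sets that differ between LowCORT and Sham could lie in the 4 arrays with a limma weight under 0.5 (Sham animal 6 at 0.292, LowCORT animal 20 at 0.401, and injected animals 34 at 0.281 and 35 at 0.339), in unequal 3' to 5' signal or in an unrecorded batch that follows subject number. Of the 103 probe sets, 89 were still called without the 4 arrays and 100 with the Gapdh and beta-actin differences as covariates, so neither of these is the whole source of the set. Chance in the grouping is unlikely for the count, since 1 of 100 splits, the real one, gave as many and the highest other gave 17. An unrecorded batch that follows subject number cannot be told apart from the groups, because the numbers run group by group, and the block of the first 5 numbers of each group, which kept 103, was balanced over both groups and left every fold change as it was. Adrenal removal was common to IntermediateCORT, which differed from LowCORT in 131 probe sets and from Sham in 1 (12 with the 3' to 5' covariates), so a dependence on the corticosterone dose stays open as a hypothesis. The saline drinking fluid that went with the low pellet stays open too, although 15 of the 103 (a median of 6 with divided arrays) were called in the opposite direction in injected animals on that pellet.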

How the results depend on the processing

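The 3' to 5' covariates, the subject block and the omission of 4 arrays of low weight were chosen after seeing the data, and the other alternatives were planned. Of 78 counts under an alternative, 55 stayed within 1.5 times the reported value. Quantile normalization, median centring, no filter, the trended robust prior, the unmoderated F test and averaged probe sets moved no count beyond that. Array weights gave 170 probe sets for LowCORT against Sham (reported 103), 2 for IntermediateCORT against Sham (1), 338 for IntermediateCORT against LowCORT (131), 50 for injected against LowCORT (21), 105 for injected against IntermediateCORT (12), 33 for injected against Sham (14) and 307 for any group (139). The 3' to 5' covariates gave 175, 12, 19 and 22 for LowCORT against Sham, IntermediateCORT against Sham, injected against IntermediateCORT and injected against Sham. The subject block, balanced over these groups, gave 163 for LowCORT against Sham and 33 for injected against LowCORT at unchanged fold changes. Without the 4 arrays IntermediateCORT against Sham had 2. With the 2 groups alone in the model, it had 4, injected against IntermediateCORT had 0 by limma (699 at an unadjusted p under 0.05 in the model of all arrays) and injected against Sham had 1, with fewer arrays behind the variance. The 50th percentile filter, which tests fewer probe sets, gave 6 for injected against IntermediateCORT and 5 for injected against Sham. Beside the 43 list calls, an estimated correlation gave 11, fry 28, of which 23 were among the 43, and its mixed test 3, where the estimate replaces the preset correlation of the same test and fry has another null hypothesis. Calls at an unadjusted p of 0.01 shared 46 probe sets between the corticosterone responses (14), by the looser threshold. For the other moved counts the cause was not tested. Median centring changed the share of higher calls in injected against IntermediateCORT from 58.3% to 44.4%. Of the values of named genes under an alternative, 1257 kept direction and side of the threshold, 80 lost the call, 60 gained it and 1 reversed. The reversed value was Sgk1 in injected against LowCORT with array weights, -0.0067 against 0.12, neither called, and the cause was not tested. The model of the 2 groups alone ended the most gene calls (36). For called lists 180 values kept and 78 lost the call. The planned log2(value + 16) did not apply, since the table was already on a log scale. No detection calls came with the table, so signal over background could not be judged for dim probe sets. No paired analysis was possible because each subject number belongs to a single animal.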

Other observations

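The tests of marker means and of the 3' to 5' covariates were chosen after the results were seen, and so were the bounds for the splits, while the list tests were planned. The mean of the interferon response list over 10 genes was 0.18 above Sham in LowCORT (95% interval 0.14 to 0.21) and 0.07 above Sham in the injected group (0.04 to 0.10). IntermediateCORT differed from Sham by -0.0038 (-0.036 to 0.028). For injected against Sham camera did not pass, with an adjusted p of 0.077, and 0.178 with an estimated correlation. Directional fry passed there (adjusted p = 0.00327). Against IntermediateCORT the injected group passed by directional fry (adjusted p = 6.58e-04) and not by camera (adjusted p = 0.0858, and 0.189 with an estimated correlation). The mean of the 16 microglial markers differed from Sham by 0.11 (SE 0.03) in LowCORT, 0.06 (SE 0.03) in the injected group and -0.03 (SE 0.03) in IntermediateCORT, and the mean of the 16 vessel markers by 0.08, 0.07 and -0.03 (each SE 0.02 or 0.03), in the same order of groups. Sgk1 and Sult1a1, both known glucocorticoid targets, parted in the injected group, where Sgk1 averaged 8.05 against 9.43 in Sham and Sult1a1 8.33 against 8.30. Dbp averaged 10.00 in LowCORT, 10.09 in the injected group, 9.75 in IntermediateCORT and 9.61 in Sham.

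Higher interferon response genes in LowCORT could come from a larger share of microglia or of vessel cells in the tissue. Such cells would bring their abundant transcripts along. The 6 most abundant microglial markers tested (Ctss, C1qb, Coro1a, Aif1, Lyz2 and C1qc) differed between LowCORT and Sham by a mean of 0.012 (95% interval -0.052 to 0.076), and the 6 most abundant vessel markers (Slc2a1, Slco1a4, Abcc9, Anpep, Vwf and Flt1) by 0.071 (-0.0067 to 0.15), both below the 0.18 of the interferon list. The mean of the 6 vessel markers rested on Slco1a4, which had 0.56 (adjusted p = 4.21e-04). Slc2a1, Abcc9, Anpep, Vwf and Flt1 had -0.025, -0.056, -0.076, 0.034 and -0.0046, and none of these passed. The interval of the 6 microglial markers lay below that of the interferon list (0.14 to 0.21). For these markers, this argues against a larger share of microglia as the whole source. The interval of all 16 microglial markers (mean 0.11, 0.057 to 0.17) overlapped that of the interferon list, as did that of the 6 vessel markers. A larger share of either cell type is therefore not excluded, and shares of other cell types were not tested. A change of these genes within cells, which may follow the corticosterone state, stays open too, as a hypothesis found and tested on the same data.

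Lower presynaptic vesicle genes in the injected group may in part reflect RNA or cDNA length. The list mean was -0.15 (SE 0.08) from Sham, and with the Gapdh and beta-actin 3' to 5' differences as covariates it was -0.04 (SE 0.05), 29.0% of the difference, while the difference of -0.13 (SE 0.08) from IntermediateCORT became 0.0019 (SE 0.06), which leaves -1.47%. LowCORT, without injections, was as low, at -0.16 (SE 0.08) from Sham, and there -0.10 (SE 0.05, interval -0.20 to 0.009) or 61.5% was left with the covariates, which does not decide for or against unequal 3' to 5' signal. Without covariates the 95% intervals of these list means all reached 0. They were -0.31 to 0.0056 for injected against Sham, -0.29 to 0.034 for injected against IntermediateCORT and -0.32 to 4.5e-04 for LowCORT against Sham. The injected group differed from LowCORT by a mean of 0.0051 in this list, so the lower level was not particular to the animals with injections. After group means were removed, the list mean had r = -0.864 with the first residual component, with 17 of 20 members negative. That component went with the Gapdh difference between 3' and 5' probe sets. Unequal 3' to 5' signal and a lower level on the low pellet both stay open.

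Chance in the grouping of the arrays is unlikely for the counts of probe sets that no other split reached, although 100 splits cannot give a bound below 1 in 100. Of 100 splits, the real one included, 1 gave as many calls for IntermediateCORT against LowCORT (131 real, highest other 1), 1 for injected against IntermediateCORT (12, highest other 1), and 1 for any of the 4 groups (139, highest other 64). The 12 calls became 0 with the 2 groups alone in the model and 6 with the 50th percentile filter. For injected against LowCORT 2 splits gave as many (21, highest other 107) and for IntermediateCORT against Sham 2 (1, highest other 5). In both, another split gave more calls than the real one, so chance is not firmly excluded for these counts. For injected against Sham 5 splits gave as many (14, highest other 189), so that chance cannot be excluded there. The 107 and 189 calls are several times the real counts and point to a structure of the samples apart from the groups. For the gene lists, chance is unlikely for the total of 43 calls with the preset correlation (1 split, highest other 31). It cannot be excluded for each call, since other assignments gave a median of 11. Chance is also unlikely for the total of 11 with an estimated correlation (1 split, highest other 1). For the 14 probe sets shared by the corticosterone responses, 1 split gave as many (highest other 0). Other assignments called few probe sets that could be shared (a median of 0 by the F test for any of the 4 groups). This count therefore does not decide whether the overlap is due to chance.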
